A study of Homo sapiens with 34 samples.

How the data were processed

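The series profiled U2OS osteosarcoma cells by CUT&RUN on 500000 cells per reaction, fixed in 0.1% formaldehyde for 1 min and sequenced as paired reads of 150 bases, per the labels' protocols. Of 34 samples, 20 libraries for SMARCA1, OGG1 and Orc6 had a list of called regions, in 10 groups of 2. Groups and replicate numbers came from the sample titles. The other 14 samples, among them IgG, SMARCA5 and siOrc2 libraries, were not analysed here.

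The submitters' processing notes name Bowtie2, SAMtools, SEACR 1.1, bedtools, deepTools, DiffBind and DESeq2 with the build hg38, without roles. Per the labels and the layout of the files, each list holds regions called in 1 library, with the authors' total signal and maximum signal of each region as whole numbers. The normalization and control behind the deposited signal are not given in the sources used here, so signal was read only to rank or filter regions within a list, and counts of reads are unknown. Signal per base makes up 2 of the 16 comparisons between antibodies and counts in their adjustment, but is not reported for that reason. The authors' deposited tables of SMARCA1 windows named up and ns give positions only, and which samples they compare is not given in the sources used here. Regions on chromosomes 1 to 22 and X were used.

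Gene positions came from a table of the GRCh38.p14 annotation with symbols, start and end but no strand, exons or introns. The planned promoter windows were therefore replaced by windows of 1 kb on each side of both ends of a gene, called gene ends. A gene was occupied in a library when a region overlapped such a window by at least 1 bp. The windows of 19970 protein-coding genes cover 2.39% of the span. Genome span was taken as the farthest region end of each chromosome, 3.03 Gb in sum.

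With groups of 2 the exact permutation test alone cannot go below p = 0.333, so library measures were tested by exact two-sided permutation of the treatment or siRNA label within strata of antibody and the other factor. Gene occupancy was tested per gene by Fisher's exact test of 4 against 4 libraries, with Benjamini-Hochberg adjustment over genes occupied in exactly 4 of 8, the sole total that can reach p = 0.0286. All 35 splits of 8 libraries were counted. In the same-number check, replicate 1 had the longer list in 5 of 10 groups (sign test p = 1, exact). The labels give the replicate number as a batch for these samples, so the numbers pair the samples, and each library-level permutation test was repeated with that block, with the blocked p-values adjusted over the same families. No 2 libraries held identical lists. The highest Jaccard index of a pair was 54.3%, among the 6992 regions of highest total signal in each library. Permutation p-values of correlations used 100000 draws.

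There were 19 gene lists, all of whose members were found in the annotation. Each was tested per group by Fisher's exact test on genes occupied in both replicates, and for its change relative to all genes by the exact permutation test. Genes were named by a rule: genes occupied in all libraries of one arm and none of the other, list members first (at most 15 per direction) and then the 10 others of highest mean percentile of total signal, or the largest difference where under 10 genes qualified. Where the text gives all members of a list behind a count, those beyond 15 were chosen after their values were seen, and not every gene of the rule is printed. A gene that this rule names is not reported here. Choices of groups, tests, lists, this rule and 118 of the alternatives were made before the data were examined, and 26 alternatives were added afterwards, as were the tests of a list's change and of differences between antibodies. Tested on simulated data of the same 19970 genes, the gene test recovered 100% of 200 changed genes in each of the 4 comparisons of 4 against 4, and unchanged data gave 67 genes of all-or-none pattern for SMARCA1 with H2O2, 32 for OGG1 with H2O2, 74 for SMARCA1 with siOrc6 and 48 for OGG1 with siOrc6. The changed genes were set to all of one arm and none of the other, so their recovery is given by construction and checks the count of the pattern, not the power to find weaker changes. The unchanged data gave all libraries the same mean occupancy and drew each gene on its own. Their counts therefore leave out differences in list length and regions shared by neighbouring genes, and are not a null for the real lists. Alternatives covered the window size, overlap, list length, bases covered, region width, signal rank, block, replicates left out and annotation span. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and bedtools 2.31.1 were used.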

Results

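Chromatin occupancy of 3 proteins was measured by CUT&RUN, in which an antibody-tethered nuclease releases the DNA next to its target. The cells were U2OS, a human osteosarcoma line, collected in early S phase after a thymidine block and a release of 3 h. The antibodies were against SMARCA1, an ATPase of the ISWI chromatin remodellers, OGG1, the glycosylase that removes 8-oxoguanine from oxidised DNA, and Orc6, the smallest subunit of the origin recognition complex. Cells carried a control siRNA (siGl3) or an siRNA against Orc6 (siOrc6) for 72 h and were left non-treated or given 5 mM H2O2 for 30 min. The series holds 34 samples in 18 groups, and 20 libraries in 10 groups of n = 2 had a list of called regions. SMARCA1 and OGG1 were profiled under both siRNAs and both treatments, and Orc6 in siGl3 cells under both treatments. The other 14 samples were not analysed here. Region lists hold no read counts, so depth is unknown. No expression was measured, so the lists do not check the knockdown. The ends of ORC6 itself, at chromosome 16, 46689659 to 46698394, were occupied in 1 of 2 non-treated and 2 of 2 H2O2 SMARCA1 libraries under each siRNA.

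H2O2 was followed by longer region lists for SMARCA1 and OGG1. SMARCA1 libraries of siGl3 cells held 9014 ± 2860 regions (mean ± SD, n = 2) without treatment and 58499.5 ± 16160.9 after H2O2. OGG1 libraries of siGl3 cells went from 19508.5 ± 2398 to 121352 ± 15094 regions (n = 2 each). In siOrc6 cells SMARCA1 lists held 12901.5 ± 2672 and 50237 ± 21010 regions, and OGG1 lists 26097 ± 10378 and 102854.5 ± 41795. The fold of the geometric means was 6.53 for SMARCA1 and 6.22 for OGG1 in siGl3 cells, and 3.76 and 3.93 in siOrc6 cells. Orc6 lists held 43533.5 ± 28508 and 45045.5 ± 11160 regions, a fold of 1.15. Over the 5 strata of antibody and siRNA the region number rose by 1.89 on the log2 scale (exact two-sided permutation p = 0.000772 over 7776 arrangements). For SMARCA1 or OGG1 alone the smallest p the design allows is 0.0556, which both gave, and for Orc6 alone it is 0.333 (exact test). The bases covered rose as well, from 161.6 to 407.1 Mb on average (exact p = 0.000772), most of it in OGG1. OGG1 lists went from 227.6 to 726.5 Mb, higher in 4 of 4 pairs (exact permutation p = 0.0556). SMARCA1 lists went from 68.5 to 106.7 Mb, higher in 3 of 4 pairs (exact permutation p = 0.167). The median region width fell by 2198 bp over the strata (exact p = 0.00772), though for Orc6 alone it was 4273 bp without treatment and 5922 bp after H2O2 (exact p = 0.667).

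**Figure D1:**
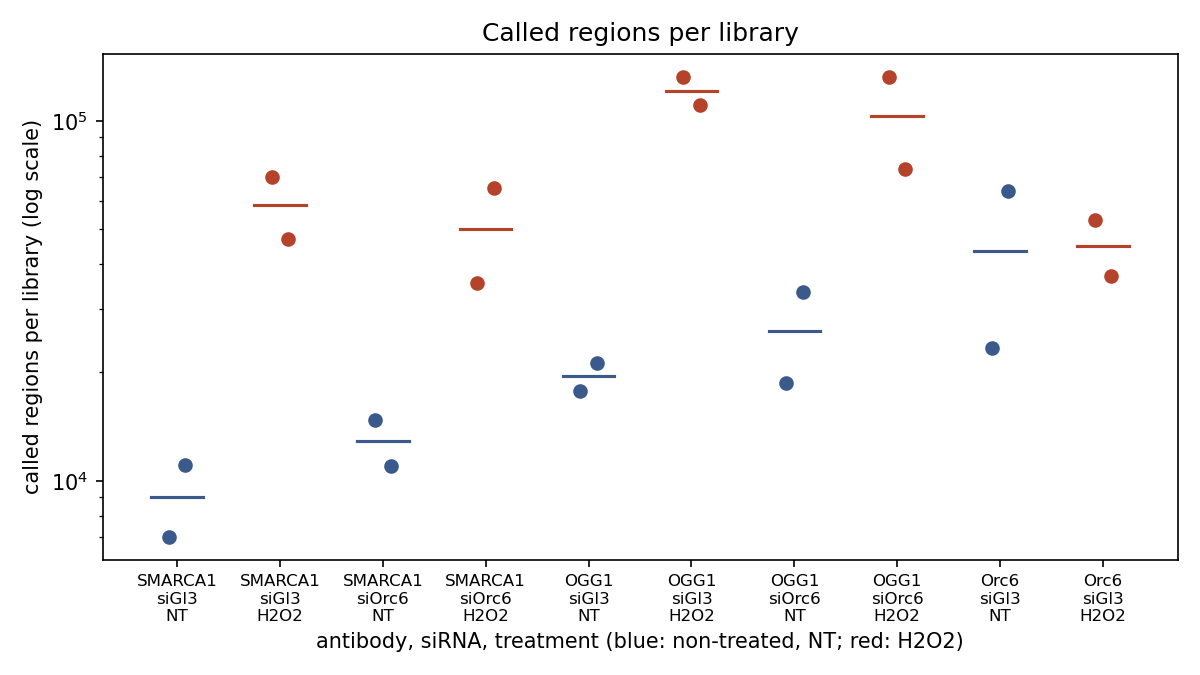
Called regions per library on a log axis, with 2 points per group of antibody, siRNA and treatment and a bar at their mean. The SMARCA1 and OGG1 libraries after H2O2 lie above the non-treated ones of the same antibody, and the Orc6 libraries overlap, at 23375 and 63692 regions without treatment and 52937 and 37154 after H2O2.

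The number of called regions showed no passing difference between siOrc6 and control cells. The mean log2 difference, siOrc6 minus siGl3, was 0.09 over the 16 SMARCA1 and OGG1 libraries (exact two-sided permutation p = 0.702), 0.14 for SMARCA1 and 0.04 for OGG1. It averages opposite differences: the fold was 1.45 for SMARCA1 and 1.29 for OGG1 without treatment, and 0.836 and 0.815 after H2O2. Single pairs ran from -0.98 to 1.08 on the log2 scale. The change with H2O2 was lower in siOrc6 than in siGl3 cells by an interaction of -0.73 on the log2 scale, which missed the threshold (exact p = 0.0926). The sign of the siRNA difference rested on a single library: without OGG1 siOrc6 NT replicate 2 (NT stands for non-treated) it was -0.02.

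A smaller share of regions lay at gene ends after H2O2. Regions within 1 kb of either end of a protein-coding gene made up 38.3% of the lists on average without treatment and 20.7% after H2O2, so the share fell by 17.7 points (exact two-sided permutation p = 0.00257). OGG1 lists went from 43.2% to 16.6% and SMARCA1 lists from 40.8% to 22.8%, while Orc6 lists stood at 23.7% and 24.6%. Relative to random placement of the same regions, SMARCA1 hardly changed, from 3.78 to 3.66 times in siGl3 and 5.17 to 5.06 in siOrc6 cells. OGG1 fell from 3.56 to 1.77 and from 3.16 to 1.98 times, and Orc6 went from 2.93 to 2.40. The change of this ratio over the strata did not pass. The direction of the share itself turned when lists of equal length were compared. Among the 6992 regions of highest total signal in each library the share rose by 7.54 points with H2O2 (exact p = 0.0221). Region width was not matched in these cut lists, and random placement was computed for full lists only. For OGG1 siGl3 H2O2 the mean share was 15.3% in full and 60.6% in cut lists, so the turn is not a comparison of like regions. Across the 20 libraries the share at gene ends was lower in longer lists (Pearson's r = -0.69, permutation p = 0.00077; Spearman's rho = -0.78, permutation p = 4e-05; adjusted p = 0.00154 and 0.00016 over 4 relations). Without the 2 libraries farthest from the median, r was -0.86. Within the 8 OGG1 libraries r was -0.96 and rho -0.98 (permutation p = 0.00014 and 0.00055). The OGG1 H2O2 lists, of 73301 regions or more, were all longer than the non-treated ones, of 33435 or fewer. Treatment is therefore part of this relation, and the permutation did not hold it fixed. Among the OGG1 H2O2 lists alone the share was 21.1% in the shortest and 14.4% in the longest. Within the 8 SMARCA1 libraries the relation did not pass, with r at -0.49 and rho at -0.52 (permutation p = 0.223 and 0.195). In lists of equal length rho was 0.15 (permutation p = 0.528).

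Groups differed in how far their replicates overlapped. The share of the shorter list overlapped by the other replicate ran from 49.9% in SMARCA1 siGl3 H2O2 to 93.3% in SMARCA1 siOrc6 NT, with a median of 81.6% over the 10 groups. Longer lists overlap more by placement alone, and bases shared relative to chance gave another order. They ran from 2.77 times in OGG1 siGl3 H2O2 to 41.8 times in SMARCA1 siGl3 NT, with SMARCA1 siGl3 H2O2 at 10.8 times. By shared bases, 10 of the 20 libraries had their own replicate as the nearest library. OGG1 siOrc6 NT replicate 2 stood apart: it shared 18.4% of bases with its own replicate and 37.8% with OGG1 siOrc6 H2O2 replicate 1. It also shared 28.9% to 35.6% with the 4 Orc6 libraries, against 18.2% and 18.1% with the OGG1 siGl3 NT libraries. SMARCA1 siGl3 NT replicate 1 was the sparsest library, with regions at 7.88% of protein-coding genes against 21.7% in its replicate.

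More genes carried a region at an end after H2O2, by 26.6 points for OGG1 and 26.5 for SMARCA1. In the full lists single genes passed for OGG1 alone. The share of 19970 protein-coding genes occupied went from 42.7% to 65.8% on average over the 3 antibodies, a rise of 23.1 points (exact two-sided permutation p = 0.000514). For OGG1, 1472 genes were occupied in all 4 H2O2 libraries and in none of the 4 non-treated ones, and 0 genes showed the opposite. All 1472 passed (Fisher's exact test, n = 4 against 4, adjusted p = 0.0345 over the 1777 genes that could pass, every gene with 4 of 4 libraries against 0 of 4). At an unadjusted p under 0.05 the counts were the same, 1472 and 0. With the replicate number as a block the smallest p a gene can reach is 0.125 (exact sign test), so no gene can pass. The count was also tied to list length: with each OGG1 list held to 17813 regions, 80 genes had the pattern, 42 of them among the 1472 (adjusted p = 0.289, Fisher's exact test), and with each list held to 165.7 Mb of covered bases 12 had it and 153 the opposite. Without OGG1 siOrc6 NT replicate 2 the count was 2278.

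Replication-dependent histone genes, which supply histones for newly made DNA, were more frequent than other genes among those that gained OGG1 in the full lists. Of 50 listed, all on chromosome 6 between 26017032 and 27893891, 18 were among the 1472, or 18 adjusted over the list alone (exact p = 0.0302). Among genes occupied in some but not all OGG1 libraries these were 18 of 42 histone genes (42.9%), against 14.3% of other genes (odds ratio 4.49, Fisher's exact adjusted p = 0.000142 over 19 lists). Genes were the units of this test, and histone genes lie close together with some sharing a region, so they are not independent. After H2O2, 33 of the 50 in siGl3 and 37 in siOrc6 cells were occupied in both OGG1 replicates, and in lists of 6992 regions 1 and 5 were. H3C1 and H4C1 lay in regions at the 90.6th percentile of total signal in the H2O2 libraries. H2AC4 was at the 85.5th, H1-1 at the 85.7th, and H2AC6 with H2BC4 at the 80.8th. H2AC7, H2BC7 and H3C4 shared a region at the 78.4th percentile. Among double-strand break repair genes 4 gained OGG1 after H2O2: BRCA2, LIG4, RBBP8 and XRCC4, of which LIG4 and XRCC4 act together in end joining. Among replication genes 4 gained it, namely GINS1, ORC3, ORC4 and ORC5. Of ribosomal protein genes 6 did (RPL30, RPS20, RPS23, RPS3A, RPS6 and RPS7), and of base excision repair genes APEX2 and NEIL3 did. Every one of these also passed when adjusted over the list alone, with no enrichment of those lists (adjusted p = 0.669 for break repair and for replication, 0.892 for ribosomal proteins and 0.909 for base excision repair). Genes of lists expected to be silent in this line were among the 1472 too, such as the hepatocyte genes G6PC1 and HP, the T-cell gene CD3E and the germline gene LDHC. Outside the lists the highest percentiles were those of OSTCP2 (99.3), SLC4A5 (99.0), AGAP5 (97.8), FITM1 (96.9), BYSL (96.6), SLC30A8 (96.2), HIF1AN (96.0), ISY1 (95.6), CCDC62 (95.0) and RNF14 (95.0). In the other direction no gene reached 4 of 4 against 0 of 4; the largest difference was 3 libraries, for TUBD1 and the mismatch repair gene MSH3.

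**Figure D2:**
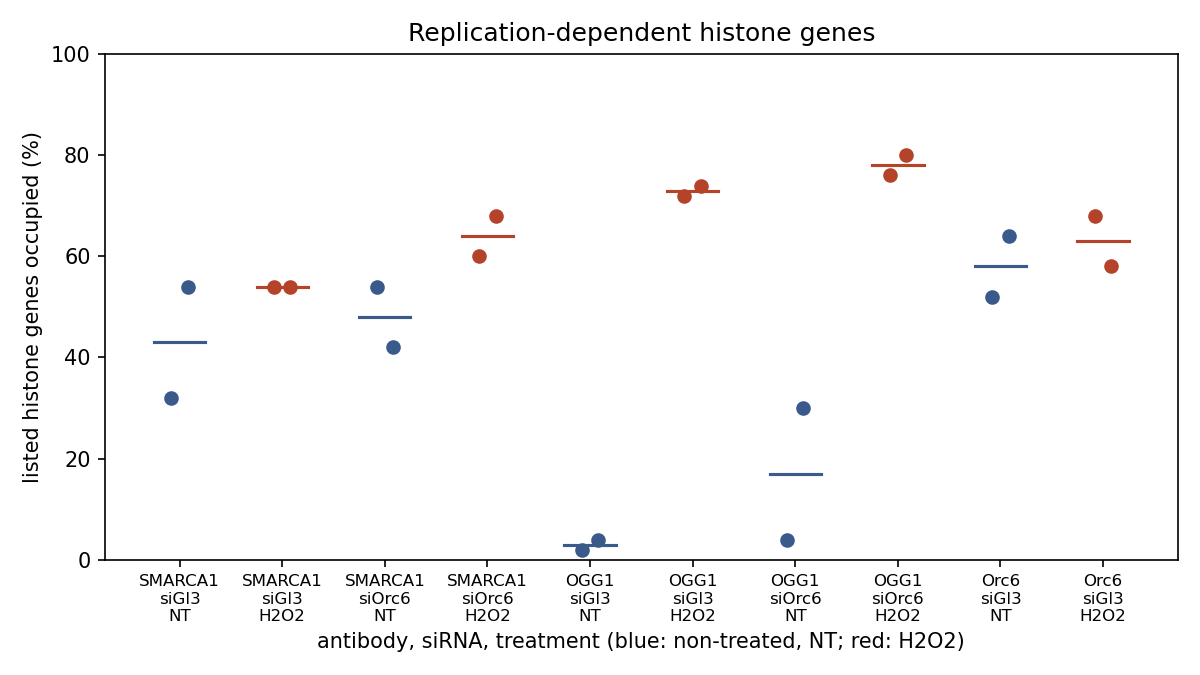
Share of the 50 listed histone genes with a region at a gene end, in percent, with 2 points per group and a bar at their mean. OGG1 siGl3 NT libraries held 1 and 2 of the 50 genes, OGG1 siOrc6 NT libraries 2 and 15, and SMARCA1 siGl3 NT libraries 16 and 27.

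For SMARCA1 the share of genes occupied was 29.3% without treatment and 55.8% after H2O2, at the smallest p the design allows (exact p = 0.0556), and no single gene passed. There were 509 genes occupied in all 4 H2O2 and no non-treated SMARCA1 library, and 5 genes with the opposite pattern. None passed (Fisher's exact test, n = 4 against 4, adjusted p = 0.108 over 1935 genes; 514 at an unadjusted p under 0.05). Among the 509 were the base excision repair genes APEX2 and POLB, which counted as 2 adjusted over the list alone (exact p = 0.0286) and 0 over all genes. They were the only testable genes of that list, so this value is the unadjusted one. The checkpoint kinase gene ATR, the remodeller genes ARID1B and HMGXB4, the p53 target SESN1, the heat shock factor gene HSF2 and the neuron gene STMN2 were members that passed neither way, except STMN2, the lone testable gene of its list (1 adjusted over the list alone). The highest percentiles outside the lists were those of NFE2 (88.9), PFKM and SENP1 (88.4 each), SPAG1 (87.4), STXBP5L (86.3), ATF7IP2 (85.5), FBXO28 (84.7), CIT (84.4), DPY19L1 (83.7) and UNC13B (83.6). The 5 genes of the other direction were GKN1, LOC124904276, MAF1, CCDC200 and TBC1D23. With SMARCA1 lists held to 6992 regions 21 genes had the pattern and 21 the opposite, and with lists held to 31.8 Mb of covered bases 232 had it and 6 the opposite; of the 21 and the 232 with the pattern, 0 were among the 509. The count was 523 without SMARCA1 siGl3 NT replicate 1.

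Orc6 regions lay at 47.7 ± 11.5% of genes without treatment and 56.9 ± 6.16% after H2O2 (SD, n = 2 each). In the 4 Orc6 libraries 566 genes were occupied in both H2O2 and no non-treated library and 64 the other way round, where Fisher's exact test cannot go below p = 0.333 (n = 2 against 2), so 0 genes pass and 0 at an unadjusted p under 0.05. The balance turned without replicate 1, at 1268 and 1943 genes, and in lists of equal covered bases, at 88 and 946; without replicate 2 it was 4598 and 278. Those with H2O2 alone included the ISWI and remodelling list members HMGXB4 and CECR2, the break repair genes PALB2 and BRCA2, TXNRD1 of the antioxidant response, RFC5, RPL14, E2F8 and HELLS, and from the lists expected to be silent STMN2, APOA2, CD79A, DAZL and ODF1. The 64 held no member of the gene lists, and the highest percentiles there were C2orf49 (99.1), SEH1L (98.9), FHL2 (97.2) and PSMG3 (94.7).

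SMARCA1 regions lay at the ends of more genes in siOrc6 than in siGl3 libraries, while OGG1 regions lay at similar shares of genes under both siRNAs. SMARCA1 occupied 14.8 ± 9.74% of genes in siGl3 and 43.8 ± 4.36% in siOrc6 non-treated cells, and 42.6 ± 2.72% against 68.9 ± 4.52% after H2O2 (SD, n = 2 each). The mean difference was 27.7 points, higher in 4 of 4 pairs of the same replicate number, at the smallest p the design allows (exact p = 0.0556). For OGG1 the difference was -1.29 points (exact p = 0.667). Over both antibodies the difference was 13.2 points (exact p = 0.0386, and 0.0859 with the replicate number as a block). The difference between the antibodies, 29.0 points, had an exact p of 0.0185 and 0.0926 after adjustment over 16 such comparisons. In all 4 siOrc6 and no siGl3 SMARCA1 library were 785 genes, and 8 showed the opposite. None passed (Fisher's exact test, n = 4 against 4, adjusted p = 0.0697 over 1935 genes; 793 at an unadjusted p under 0.05). With lists held to 6992 regions 1072 genes had the pattern and passed (adjusted p = 0.0421, Fisher's exact test), 221 of them among the 785; with the replicate number as a block no gene can go below 0.125 (exact sign test). With lists held to 31.8 Mb of covered bases 159 had it and 106 the opposite, 43 of the 159 among the 785, and none passed (adjusted p = 0.119, Fisher's exact test). All 4 SMARCA1 siOrc6 lists, and no SMARCA1 siGl3 list, bear a mark of a second submission in their names, so the siRNA and that mark cannot be told apart here.

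**Figure D3:**
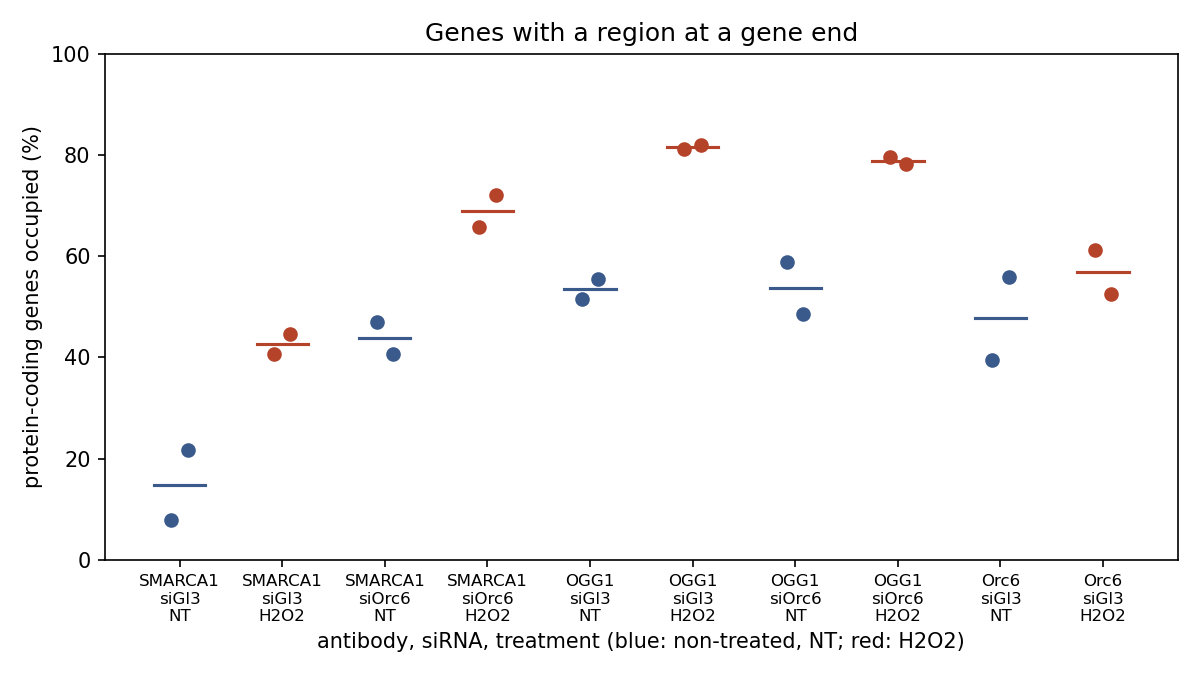
Protein-coding genes with a region at a gene end, in percent of 19970, with 2 points per group and a bar at their mean. SMARCA1 libraries average 14.8% and 43.8% in non-treated siGl3 and siOrc6 cells, and OGG1 libraries 53.6% and 53.7%.

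Genes of several lists were among the 785. The antioxidant genes GPX4, SOD2, SQSTM1 and TXN were 4 of the 31 in the NRF2 list, 4 adjusted over the list alone (exact p = 0.0429) and 0 over all genes, with an odds ratio of 3.30 for the list (Fisher's exact adjusted p = 0.688). The mesenchymal and bone genes COL6A2, SP7 and THY1, of which SP7 encodes the osteoblast factor osterix, were 3 adjusted over the list alone (exact p = 0.0286) and 0 over all genes. The remodeller genes BAZ1A, CHD3 and SMARCA4 passed neither way (exact p = 0.0571 over the list alone). MDM2 and TP53INP1 of the p53 list, RPL12, RPL14 and RPS15 of the ribosomal list, SLBP, which encodes the stem-loop binding protein of histone mRNA, and EGR2 passed over the list alone and not over all genes. PALB2, RNF8 and HYOU1 passed neither way. From the lists expected to be silent the myeloid factor gene SPI1 passed over its list alone (exact p = 0.0286) and the germline gene PRM2 did not (exact p = 0.0571). SLBP, EGR2 and SPI1 were the lone testable genes of their lists, and all testable mesenchymal and ribosomal genes had the pattern. Their value over the list alone is thus the unadjusted one (Fisher's exact p = 0.0286), with no adjustment across lists. The highest percentiles outside the lists were BICDL2 and CLDN6 (99.6 each), CCDC188 (99.5), LOC124904950 and SNX8 (99.3 each), BIRC7 and M1AP (99.1 each), and LAMA5, PCYT2 and STX10 (98.9 each). Among the 8 genes of the other direction were SLC39A10, PTCHD4, OR14A2, GPX8, TMEM244, FAP and NCOA7. For OGG1, 0 genes were in all siOrc6 and no siGl3 libraries and 1, VIPR2, showed the opposite (Fisher's exact test, adjusted p = 1; 1 at an unadjusted p under 0.05). The largest difference toward siOrc6 was 3 libraries, for H4C12, FAT1, NUDT10 and USP45.

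The 19 gene lists differed in how often their members were occupied in both replicates of a group. Of 190 tests of list and group, 79 gave more and 22 fewer occupied members than other genes (Fisher's exact test, Benjamini-Hochberg over the 190; genes are the units, so this describes these libraries). In lists of equal length the counts were 55 and 12, with 42 of the 55 among the 79. Immediate early genes such as MYC and CCN1 were above other genes in SMARCA1 siGl3 NT, with 9 of 30 occupied (odds ratio 5.92), and in SMARCA1 siOrc6 NT with 25 of 30 (8.07). The p53 targets had 9 of 28 (6.54) and 22 of 28 (5.92) in those groups, and the mismatch repair genes 6 of 23 (4.86) and 16 of 23 (3.69). In SMARCA1 siOrc6 H2O2 the base excision repair list had 28 of 30 (7.94), the ribosomal proteins 54 of 58 (7.67), the heat shock and unfolded protein response list 26 of 28 (7.37), origin licensing and replication 32 of 35 (6.05), ISWI and other remodellers 27 of 30 (5.11), G1/S and E2F targets 24 of 27 (4.54) and break repair and checkpoint 31 of 35 (4.40). The NRF2 list had 24 of 31 in OGG1 siGl3 NT (3.78). The mesenchymal and bone list passed in 1 of the 10 groups, SMARCA1 siGl3 NT, with 5 of 25 (3.44), and the genes next to mapped origins passed in none of the 10 groups, with 8 of 13 in OGG1 siGl3 NT (1.76). Of the lists expected to be silent in this line, olfactory receptors were below other genes in 9 of the 10 groups, with 0 of 35 in OGG1 siGl3 NT, and hepatocyte genes in 7, with 2 of 20 in OGG1 siOrc6 NT (0.16). Lymphocyte and myeloid genes were below in 3 groups, with 1 of 20 in Orc6 siGl3 NT (0.09) but 10 of 20 in OGG1 siGl3 NT, where other genes were at 47.6%, and germline genes in 1, with 8 of 25 in SMARCA1 siOrc6 H2O2 (0.27), while neuron genes passed in no group and had 11 of 20 in OGG1 siGl3 NT (1.35). Histone genes were above other genes in SMARCA1 siGl3 NT, with 14 of 50 (5.38), and below them in OGG1 NT, with 0 of 50 in siGl3 and 1 of 50 in siOrc6 cells (0.0289).

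Relative to all genes, the change with H2O2 was -8.77 points for p53 targets (exact adjusted p = 0.0326 over 19 lists, 0.136 with the replicate number as a block), -10.3 points for mesenchymal and bone genes (exact adjusted p = 0.0326, block 0.136) and -16.2 points for olfactory receptors (exact adjusted p = 0.00977, block 0.0742). All genes rose by 23.1 points with H2O2, so these values are smaller rises and not falls. Of the p53 targets 22 of 28 in OGG1 siGl3 NT and 21 of 28 in OGG1 siOrc6 NT were already occupied in both replicates. With siOrc6 the ISWI and remodelling list stood 8.06 points above the change of all genes (exact adjusted p = 0.0293, block 0.0742), so none of these list changes held with the block. Over all 171 tests of this kind, 0 passed and 15 had an unadjusted exact p under 0.05. P-values measure only the spread between these samples, whose separate cultures the labels do not state.

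MYC, at chromosome 8, 127735434 to 127742951, was occupied in every library of the 3 antibodies. At the head of the genes occupied in all 8 SMARCA1 libraries were HORMAD2 (mean percentile 99.5), ID1 (99.0), FOSL2 (98.8) and H3-3B (98.6), with list members such as PPM1D (96.5), RRM2 (95.4) and the ISWI subunit gene CHRAC1 (93.3). OGG1 had its widest non-treated region called in both replicates at chromosome 7, 1337439 to 1615587, across MICALL2, INTS1, MAFK, TMEM184A and PSMG3, and another at 5436528 to 5700471 across FBXL18, ACTB, FSCN1 and RNF216. HMOX1, the heme oxygenase gene of the NRF2 response, was at the 99.9th percentile for OGG1 and the 99.8th for Orc6. Orc6 had its region of highest non-treated signal at chromosome 4, 30712061 to 30794810, over the PCDH7 gene, which also held the SMARCA1 region of highest non-treated signal, 30741618 to 30771970. These values are the authors' and rank regions within a list.

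The share of Orc6 regions overlapped by SMARCA1 and by OGG1 regions was larger after H2O2 in these libraries, too few for the exact permutation test to pass. In siGl3 cells of the same batch SMARCA1 regions overlapped 19.96 ± 5.26% of Orc6 regions without treatment and 50.6 ± 0.812% after H2O2, and OGG1 regions 40.3 ± 11.8% and 91.1 ± 3.35% (SD, n = 2; the smallest exact p is 0.333). The partner lists were longer after H2O2, and the bases shared relative to chance went from 12.5 ± 4.56 to 5.55 ± 0.000854 times for SMARCA1 and from 5.47 ± 2.79 to 2.89 ± 0.219 times for OGG1. In lists of 6992 regions the difference for SMARCA1 turned to -6.46 points, and it was -7.08 points when the overlap had to cover 50% of the Orc6 region.

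The authors' deposited tables name SMARCA1 windows as up or not significant (ns) in each treatment. Windows named up lay at gene ends more often than ns windows: 71.4% of 7045 against 14.4% of 5317 in NT (odds ratio 14.9, 95% interval 13.6 to 16.3) and 65.0% of 12359 against 16.3% of 31524 after H2O2 (odds ratio 9.53, 9.09 to 9.999). They overlapped regions found in both Orc6 libraries less often, at 72.4% against 79.1% in NT (odds ratio 0.693) and 55.7% against 63.5% after H2O2 (0.723; Fisher's exact p = 7.64e-18 and 1.07e-50, two-sided). The H2O2 difference rested on Orc6 replicate 2: with Orc6 replicate 1 alone the log2 odds were -0.0051 (exact p = 0.892). Windows are not replicates, so these p-values compare the windows of these tables alone. Up windows in NT were covered by regions of both SMARCA1 siOrc6 NT libraries at 99.97% and 99.9%, and by the 2 SMARCA1 siGl3 NT libraries at 16.2% and 48.0%. Up windows after H2O2 were covered at 99.92% and 99.96% by the SMARCA1 siOrc6 H2O2 libraries, and at 44.3% and 52.1% by the siGl3 H2O2 ones. If the tables compare siOrc6 with siGl3 libraries, which is not stated, their gene-end shares restate the SMARCA1 difference above. Of 10741 loci with a window in both treatments 5234 were up in both, where independent lists would share 3470 (log2 odds 5.05). Among genes with a window, histone genes were named up less often than others, 7 of 18 in NT and 4 of 29 after H2O2 (Fisher's exact adjusted p = 2.2e-05 and 6.16e-09), while all 21 base excision repair genes with a window, among them APEX1, APLF and APTX, were up in NT, without passing against other genes (Fisher's exact adjusted p = 0.475). After H2O2 19 of 28 were up (67.9%), against 70.5% of other genes (Fisher's exact adjusted p = 0.992).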

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

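The comparisons between antibodies, the tests of region number, covered bases, antibody, resubmission, genes up to the median histone length and calling in any library, and the counts of splits were chosen after their results had been seen; the tests of genes up to the longest histone gene and of genes near the histone genes were written before.

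Differences between SMARCA1 and OGG1 in their change with siOrc6 or H2O2 had an unadjusted exact p under 0.05 in the measures that follow, of which bases within genes with siOrc6 alone passed adjustment over 16 comparisons and none did with the replicate number as a block. The percentage of genes occupied differed by 29.0 points with siOrc6 (exact p = 0.0185, adjusted 0.0926, adjusted with the block 0.188), with siOrc6 higher in 4 of 4 pairs for SMARCA1 and in 1 of 4 for OGG1. The gene-end share differed by 24.8 points (exact p = 0.0448, adjusted 0.127, adjusted with the block 0.225) and, in lists of equal length, by 39.2 points (exact p = 0.0231, adjusted 0.0926, adjusted with the block 0.188). Bases within genes differed by 7.03 points with siOrc6 (exact p = 0.00154, the smallest possible; adjusted 0.0247, adjusted with the block 0.125) and by 6.19 points with H2O2 (exact p = 0.0108, adjusted 0.0864, adjusted with the block 0.188).

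Among the lists, and relative to the change of all genes, histone genes changed by 51.9 points less for SMARCA1 than for OGG1 with H2O2, a difference of -51.9 (exact p = 0.00154, adjusted 0.0293 over 19 lists and 0.088 over all 171 list tests, adjusted with the block over the 19 0.0742). With siOrc6 the relative difference was -31.0 (exact p = 0.00617, adjusted 0.117, adjusted with the block 0.297). All genes then differed by 29.0 points the other way, which makes up most of that value. In lists of equal length the H2O2 difference was -33.6 (exact p = 0.00772), where SMARCA1 siGl3 and siOrc6 libraries held 14 and 21 of the 50 histone genes in both replicates without treatment and 8 and 5 after H2O2, and OGG1 libraries 0 and 0 and then 1 and 5. Also relative to all genes, remodelling genes differed by 9.31 points with H2O2 (exact p = 0.00772, adjusted 0.0733, adjusted with the block 0.0742), and olfactory receptors by -25.4 with siOrc6 (exact p = 0.0386, adjusted 0.367, adjusted with the block 0.544). The value for the receptors again comes from the 29.0 points of all genes, not from a fall at the receptors.

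A list of the whole series, named for Orc6 in non-treated siGl3 cells and used in no comparison, held 13557 regions, of which 77.0% lay in both Orc6 non-treated lists.

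For the gain of SMARCA1 at gene ends after siOrc6, a larger number of regions alone is argued against: in lists of 6992 regions the count was 1072 against 785, though 221 genes were in both. Wider regions stay open, since siOrc6 libraries had a median width higher by 1483 bp (exact p = 0.0556, 4 of 4 pairs) and lists of equal covered bases gave 159 genes, 43 of them among the 785; so does depth, which is unknown for these lists. An effect on every antibody is open as well for these genes: OGG1 gave 0 such genes, but 0 of the 785 were free of OGG1 in its 4 siGl3 libraries, so none could be gained there. Over all genes the values argue against an equal gain, at -1.29 points for OGG1 (pairs -7.06 to 7.34) and 27.7 for SMARCA1 (pairs 19.1 to 39.0). The difference between the antibodies did not pass adjustment, though (exact permutation, adjusted p = 0.0926). In 1 of the 35 splits of the 8 libraries, the real one, there were as many genes (793 in both directions; the highest other was 514, the split by treatment), while the 8 splits that part all 4 pairs of the same replicate number, where the highest other was 7, are too few for a share under 0.05. Separate processing may also be the source: 4 SMARCA1 siOrc6 lists and 0 siGl3 lists carry the second-submission mark, so the 2 cannot be told apart.

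For the OGG1 absence at histone genes in non-treated cells, short span as the whole cause is argued against: the 83 other genes of at most 487 bp, the median span of the listed genes, were occupied in both siGl3 libraries at 18.1% in OGG1 as in Orc6, while histone genes were at 0 of 50 in OGG1 and 26 of 50 in Orc6 (Fisher's exact p = 0.00101 and 7.89e-05 against the short genes, with genes as the units). Histone genes lie close together and can share a region, so they are not independent units in these tests. Genes up to the longest listed one (13229 bp), the limit set beforehand, were at 45.2%, but that limit took in genes that are not short. Copy loss or unmappable sequence of the cluster is argued against, since 52.0% of the histone genes were occupied in both Orc6 libraries and 28.0% in both SMARCA1 libraries, which also excludes that they cannot be called. The test written for it met its own bound, at 0 of 6 neighbouring genes in both OGG1 libraries (0%), but H1-6, H4C7 and H2AC15 among the 6 are themselves histone genes, H2AC15 was occupied in 1 of 2 OGG1 siGl3 NT libraries, it and TRIM38 were occupied in both Orc6 NT libraries, and HFE and OR2B2 in no library, so that bound could not separate the cases. The listed histone genes all lie on chromosome 6. Its share of region bases over its share of the span was 0.371 and 0.392 in OGG1 siGl3 NT. In Orc6 NT it was 0.559 and 0.689, and in OGG1 siGl3 H2O2 0.687 and 0.641. In OGG1 siOrc6 NT it was 0.387 and 0.569, with 2 and 15 of the 50 histone genes occupied. A trait of the whole chromosome in these lists therefore stays open. A lower OGG1 signal over the cluster before damage may also be a biological difference, which was not tested. Lists of equal length held 1 of 50 histone genes in siGl3 and 5 of 50 in siOrc6 cells after H2O2. These counts cannot decide whether the gain with H2O2 goes with list length. The cut keeps 6992 of 73301 to 132408 regions in the OGG1 H2O2 lists, so regions below the top ranks drop out in any case.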

How the results depend on the processing

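Alternatives that left out a single library, used the gene span, held lists to equal covered bases, compared the antibodies or set the share against random placement were chosen after seeing the data, and so were the main tests between antibodies.

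Of 144 alternatives, 103 kept direction and side of the threshold, 10 were weaker, 1 was stronger, 25 moved a count or value and 5 reversed it. Depth is unknown for these lists, so list length stood in for it. Lists of equal length were not matched for region width. With lists of equal length the gene-end share with H2O2 turned to 7.54 points, the Orc6 share overlapped by SMARCA1 to -6.46 points and the relation of share and region number to 0.15, while the Orc6 share overlapped by OGG1 moved to 19.7 points. The counts of genes then were 21 for SMARCA1 and 80 for OGG1 with H2O2, and 1072 for SMARCA1 and 10 for OGG1 with siOrc6. In lists of equal covered bases they were 232 for SMARCA1, 12 for OGG1 and 88 for Orc6 with H2O2, and 159 for SMARCA1 and 1 for OGG1 with siOrc6. Among regions above the median total signal of each list they were 1017 and 2456 with H2O2. With an overlap of 50% of the region the gene-end share changed by -3.61 points (exact p = 0.132) and the Orc6 share overlapped by SMARCA1 by -7.08. Measured as a share of bases the gene-end change was -1.84 points (exact p = 0.253), and as a ratio to random placement -0.748 (exact p = 0.062). Within SMARCA1 the relation was -0.52. With the gene span SMARCA1 counts were 1002 with H2O2 and 452 with siOrc6.

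Leaving out each replicate number gave 1.48 to 2.29 for the log2 change of regions with H2O2 and -20.2 to -15.1 points for the gene-end share, which end both calls because 1 library per group is left. Together with the single libraries left out, the ranges were -0.0162 to 0.13 for the log2 difference in regions with siOrc6, whose sign turned without OGG1 siOrc6 NT replicate 2, 523 to 1966 genes for SMARCA1, 2278 to 3511 for OGG1 and 1268 to 4598 for Orc6 with H2O2 (against 1943 and 278 the other way round), 791 to 2733 for SMARCA1 and 1 to 46 for OGG1 with siOrc6, and -0.75 to -0.0051 for the log2 odds of Orc6 overlap of up windows after H2O2. With fewer libraries more genes meet an all-or-none rule by construction; for the other changes the cause was not tested. With the replicate number as a block, the 1472 OGG1 genes had p = 0.125 (exact sign test), the smallest possible. All 5 list changes that passed over 19 lists, the antibody difference in histones among them, were lost with the block (0 passed), and so was the antibody difference in bases within genes. Besides these and the block values printed beside their results, it changed no other call among the results reported and run with it. No block was run for gene counts in lists of equal length or equal covered bases, where no gene can go below 0.125 (exact sign test) either.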

Other observations

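The splits of the samples and the tests of a calling threshold and of a common response were chosen after their results had been seen.

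Other gene classes were also occupied at higher mean shares in the H2O2 lists of siGl3 cells, counting a region anywhere in the gene or within 1 kb of it. Transfer RNA genes (443) were occupied at 6.55 ± 5.11% in SMARCA1 siGl3 NT and 38.3 ± 2.08% after H2O2, at 26.6 ± 1.60% and 67.7 ± 1.28% for OGG1, and at 49.0 ± 8.30% and 57.6 ± 0.958% for Orc6 (SD, n = 2). Small nucleolar RNA genes (1196), many of them inside host genes, were at 15.9 ± 4.43% and 56.2 ± 3.84% for OGG1 in siGl3 cells, and at 7.98 ± 1.71% and 17.02 ± 4.20% for SMARCA1. Small nuclear RNA genes (154), which encode the spliceosomal RNAs among others, were at 19.8 ± 2.30% and 55.5 ± 0.459% for OGG1. In siOrc6 cells small nucleolar RNA genes stood at 14.9 ± 2.78% and 16.4 ± 4.32% for SMARCA1, a difference less than either SD. The OGG1 siGl3 lists covered 6.77% of the span without treatment and 26.4% after H2O2, and wider coverage alone raises such shares. No test was made of these values.

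In lists of equal length, SMARCA1 siOrc6 NT lists had a mean Jaccard index of 29.7% with OGG1 siGl3 NT and 19.6% with SMARCA1 siGl3 NT lists. After H2O2 the order was the other way round, with 9.38% for OGG1 siGl3 and 13.8% for SMARCA1 siGl3 lists. The series-level list named for Orc6 covered 79.8 Mb and had 46.6% of its regions at gene ends.

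The number of regions rose with H2O2 and a lower calling threshold may be part of it. In lists of equal length the Jaccard index between treatments relative to that between replicates ran from 0.657 to 1.20 over the 5 strata, under 0.75 in 3 of them, which leaves this open. A response common to the 3 antibodies is also open: the log2 change in siGl3 cells differed by up to 2.51 (exact p = 0.491 over 216 arrangements), while the mean of SMARCA1 and OGG1 minus Orc6, a contrast formed after Orc6 was seen to differ, was 2.47 (exact p = 0.0463).

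Of the 35 splits, 2 gave as many genes as the H2O2 split of SMARCA1 (514 in both directions): the real one and the split by siRNA (793, the highest other), itself a comparison of the design, with a median of 3 over all splits but the real one, so this count does not decide on chance there. For OGG1 with H2O2 1 of 35 did, the real one (1472; highest other 108), and for OGG1 with siOrc6 27 of 35 did (1 gene; highest other 1472, the split by treatment). The numbers pair the samples, and the 8 splits that part all 4 pairs are too few for a share under 0.05; among them the highest other was 20 for SMARCA1 and 108 for OGG1 with H2O2.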
